A study of Mus musculus with 12 samples.

How the data were processed

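Polyadenylated RNA was measured in 12 libraries of retinal cells from adult male wild-type mice, 3 in each of 4 groups set by the virus (AAV-GFP or AAV-Olig1) and the days after optic nerve crush (7 or 14). Per the labels' protocols, virus was injected into the vitreous, cells were separated with CD90.2 beads, fluorescent cells were picked with a Unipick device, and cDNA was made with the SMART-Seq HT kit and 20 PCR cycles. The number of cells per pool is given differently in different labels, within 10 to 20. A virus time of 14 days is recorded for every library at both days after the crush, and time since injection did not enter any test. The labels speak of several batches of libraries without saying which library belongs to which, so batch could not enter any test. Spike-in RNA is named in the labels' protocols as a quality control and was not analysed here.

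The deposited values were raw counts of reads per Ensembl gene, in 1 table per sample and 1 table for the series, which the authors made, per the submitters' processing notes, with FastQC, HISAT2 and HTSeq on mm10. Versions, annotation release and strand setting are not given in the sources used here. All values were whole numbers. Among the 12 libraries, the per-sample files of 4 ended in the middle of a line and lacked 270 genes (Olig1 day 7 replicate 2), 1193 genes (GFP day 14 replicate 1), 1452 genes (GFP day 14 replicate 3) and 2853 genes (Olig1 day 14 replicate 3). These genes were filled from the series table and held 2.73%, 6.85%, 7.36% and 14.0% of the counts of those libraries. Of the genes present in both sources, 0 differed. The table had 54232 genes, of which 54165 were given a symbol and coordinates from GENCODE M21 on GRCm38 and 67 had none. No HTSeq summary lines were in the tables.

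Total counts per library ran from 12534515 to 27602459. A count of 0 allowed up to 3 counts of the total. Same-group libraries correlated at 0.596 to 0.815 (12 pairs) and libraries of different groups at 0.507 to 0.681 (54 pairs) across genes, and no pair was a duplicate. Total count, genes detected and the share of the top 50 genes were compared between arms by exact permutation tests, 3 against 3 at each day (smallest adjusted p over 14 tests 0.622). The common biological coefficient of variation was 1.351.

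Counts were tested with edgeR 4.0.16 (quasi-likelihood, robust, TMM scaling, filterByExpr by group with a minimum count of 10) in R 4.3.3, with 1 fit of all 12 libraries on the 4 groups and no covariate. The filter left 14985 genes. The contrasts were Olig1 against GFP at day 7, at day 14 and over the mean of both days, the difference between the days (interaction), and day 14 against day 7 within each virus. Calls were made at a Benjamini-Hochberg adjusted p of 0.05 with no fold threshold. Where a group had 0 counts a bound from 3 counts replaced the fold, and with 1 to 3 counts in the low group a ratio of pooled counts, scaled by the totals, with a 95% exact binomial counting interval. Table work and figures used Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

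The 49 gene lists (17 of cell type markers and 32 of functions) were written before the data were examined. So were the contrasts, tests, thresholds, the rule for named genes and the alternatives. The lists held 946 entries, all found in the table, and some genes, such as Jun, were in several lists. Of the lists, 48 had at least 3 tested genes, and the T cell list had 0. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a contrast, with an estimated correlation and fry (directional) beside it. Fry tests each list alone and does not compare it with other genes. Marker sums are CPM summed over each cell type list and were compared by exact two-sided permutation tests of log2 sums with a pseudocount of 1 CPM, for which 3 against 3 cannot go below 0.1.

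Genes were named by a fixed rule: Olig1; the 10 largest rises and 10 largest falls among called genes whose arms did not overlap, without predicted gene models; up to 4 called members of each called list, or else the 2 with the smallest p; and a panel of 26 genes. Some genes that the rule picks are left out of the text. For the remaining contrasts the 5 largest or 5 smallest p on each side were named. Igkc, Jchain, Ighm, Penk and the list members outside this rule were named after their values were seen. Because the strand setting is not given, exon overlaps were checked. Rpgrip1 shares 1057 bases with Supt16, Nefl 1108 with Nefm, Fdft1 774 with Ctsb, Atp5j 397 with Gabpa, Srsf2 460 with Mettl23, and Nudcd1 266 with Eny2, all on opposite strands. Olig1 shares 157 bases with Gm15966, which had 1 count. CT010467.1 overlaps Gm42418, and Tgtp1 and Ifit3 have close paralogs, so reads of these genes cannot be assigned with certainty.

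Alternatives were DESeq2 size factors in the edgeR test, the DESeq2 1.42.0 Wald test, limma voom with sample weights, no filter, at least 10 counts in at least 6 libraries, a replicate block, the series table, a fit of only the groups compared, an adjusted p of 0.1 for the overlap between days, and leaving out each library in turn. Using only genes in all per-sample tables, and leaving out GFP day 14 replicates 1 and 3 together, were chosen after the data were seen. Replicate numbers were not treated as pairs. Library labels were also regrouped, in all 10 splits of 3 against 3 or 60 draws for the mean and the interaction.

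The procedure was tested on simulated data for the 14985 genes, 200 of them changed. The filter left 14524 of these, with 49 or 50 changed genes at each fold. EdgeR recovered 0%, 12.0%, 42.9% and 55.1% of genes changed 4, 16, 64 and 256-fold at day 7, with 8 false calls. It recovered 2.04%, 18.0%, 40.8% and 57.1% at day 14, with 1 false call, and 6.12%, 40.0%, 69.4% and 77.6% over both days, with 9. The false calls numbered 215, 244 and 206 with DESeq2 and 10, 1 and 9 with limma voom in the same 3 comparisons. For the interaction, with nothing changed, they numbered 2, 155 and 1 for the 3 tools. EdgeR was kept as planned. Changes of 4-fold were thus mostly not detectable with these libraries.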

Results

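RNA was sequenced from 12 pools of a few fluorescent cells each, taken from retinas of adult male wild-type mice after optic nerve crush, an injury that severs the axons of retinal ganglion cells. Eyes had received an adeno-associated virus carrying either Olig1, a basic helix-loop-helix transcription factor of the oligodendrocyte lineage, or green fluorescent protein (GFP) as the control. Per the labels, cells enriched with CD90.2 beads were picked with a Unipick device as retinal ganglion cells 7 or 14 days after the crush, which gave 4 groups (GFP day 7, Olig1 day 7, GFP day 14 and Olig1 day 14) of 3 libraries. Total counts, in units of 1e6, ranged from 12.5 to 27.6 per library. The group means were 18.0 ± 0.864 (SD, n = 3) for GFP day 7, 15.2 ± 2.96 for Olig1 day 7, 25.7 ± 1.83 for GFP day 14 and 21.3 ± 2.94 for Olig1 day 14. Genes with at least 1 count numbered from 10129 (GFP day 14 replicate 1) to 17244 (Olig1 day 7 replicate 3). A count of 0 allowed up to 0.109 to 0.239 CPM (counts scaled to 1e6 per library), depending on the library. Such limits, and the counting intervals given with ratios, cover counting error only. The labels do not say that the libraries of a group came from separate animals, so p-values measure the spread between these libraries, which may be technical. Group levels are means of CPM ± SD with n = 3 libraries, fold changes are log2 values of Olig1 over GFP ± SE unless stated, and coordinates are on GRCm38.

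Whether the vector raised its own gene was asked first. Olig1 (ENSMUSG00000046160, chromosome 16, 91269772 to 91271933) stood at 0.224 ± 0.194 CPM with GFP and 667 ± 393 CPM with Olig1 at day 7. At day 14 it stood at 0.0956 ± 0.135 and 232 ± 251 CPM. Olig1 rose by 11.62 ± 1.59 at day 7 (edgeR adjusted p = 0.0113), by 11.02 ± 1.57 at day 14 (adjusted p = 0.0276) and by 11.32 ± 1.11 over the mean of both days (adjusted p = 0.000261). All 3 Olig1 libraries lay above all 3 GFP libraries at each day, for which the exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. Counts per gene cannot part the vector's transcript from the mouse gene's own. Olig2, its neighbour and relative, had 0 counts in every library. At day 7 the adjusted p was 0.0798 without GFP day 7 replicate 1 and 0.0736 without replicate 3, in a range of 1.61e-19 to 0.0798 over the 15 alternatives. At day 14 it ranged from 2.3e-16 to 0.499 over 16 alternatives. It missed the threshold without GFP day 14 replicate 1 (0.0670) or 2 (0.199) and without Olig1 day 14 replicate 3 (0.0859). It also missed it without a filter (0.125), with a replicate block (0.0648) and with only these groups in the fit (0.499). Without GFP day 14 replicates 1 and 3 together, which leaves 1 library in that group, the log2 fold change was 12.54.

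**Figure D1:**
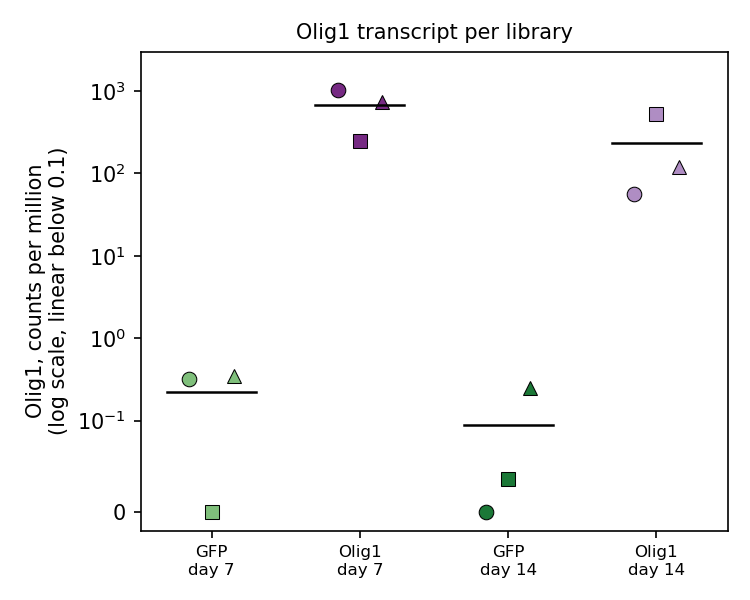
Olig1 level in each library (CPM, on a log axis that is linear at the lowest values), by group, with points for libraries and bars for group means. The 6 Olig1 libraries lie between 56.4 and 1029 CPM and the 6 GFP libraries below 1 CPM.

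Marker genes of retinal cell types showed which transcripts the pools held. The summed ganglion cell markers came to 174 ± 125 CPM with GFP and 3397 ± 1314 CPM with Olig1 at day 7, and to 177 ± 91.1 and 1310 ± 1920 CPM at day 14, where Olig1 replicate 2 alone reached 3527 CPM against 179 and 225 CPM in the other libraries. Rod markers came to 48730 ± 29755 CPM with GFP and 1143 ± 409 CPM with Olig1 at day 7, and to 31796 ± 31407 and 8414 ± 6816 CPM at day 14. Cone markers stood at 1754 ± 295 and 62.8 ± 42.1 CPM at day 7 and at 4125 ± 2553 and 325 ± 379 CPM at day 14. Bipolar markers stood at 1914 ± 442 and 398 ± 116 CPM at day 7 and at 4207 ± 2321 and 402 ± 159 CPM at day 14. Amacrine markers stood at 754 ± 278 and 2925 ± 1775 CPM at day 7 and at 632 ± 202 and 1433 ± 599 CPM at day 14. Müller glia markers were abundant in all groups, with means of 99097, 76033, 90659 and 98119 CPM in the order given at the start. Apoe, a member of this list, held 3.90% of all counts in GFP day 7 replicate 1 and 11.6% in Olig1 day 7 replicate 2. The list sums of these libraries were 68988 and 127496 CPM, so Apoe made up most of each. The median log2 fold change of the list at day 7 was -1.59. Microglia and macrophage markers were high in 4 libraries and at most 53.2 CPM in the others, the 4 being GFP day 7 replicate 3 (3200 CPM), Olig1 day 7 replicate 3 (1725 CPM) and GFP day 14 replicates 2 (7489 CPM) and 3 (10985 CPM). The labels call the pools ganglion cells. In the GFP libraries of both days, however, ganglion cell markers came to 70.6 to 313 CPM. Müller glia markers came to at least 58676 CPM and rod markers to at least 4990 CPM there. These sums argue against ganglion cells as the main source of RNA in the GFP pools. Olig1 day 14 replicates 1 and 3 lay in the same range of ganglion cell markers. For the remaining Olig1 libraries the sums leave the identity open. Immunoglobulin genes held 15.3% of the counts of GFP day 14 replicate 3, with Igkc at 74564, Jchain at 30347 and Ighm at 27573 CPM. In exact permutation tests of the 17 cell type sums at each day, 3 against 3, the smallest p was 0.1 and the smallest adjusted p over 34 tests was 0.283.

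**Figure D2:**
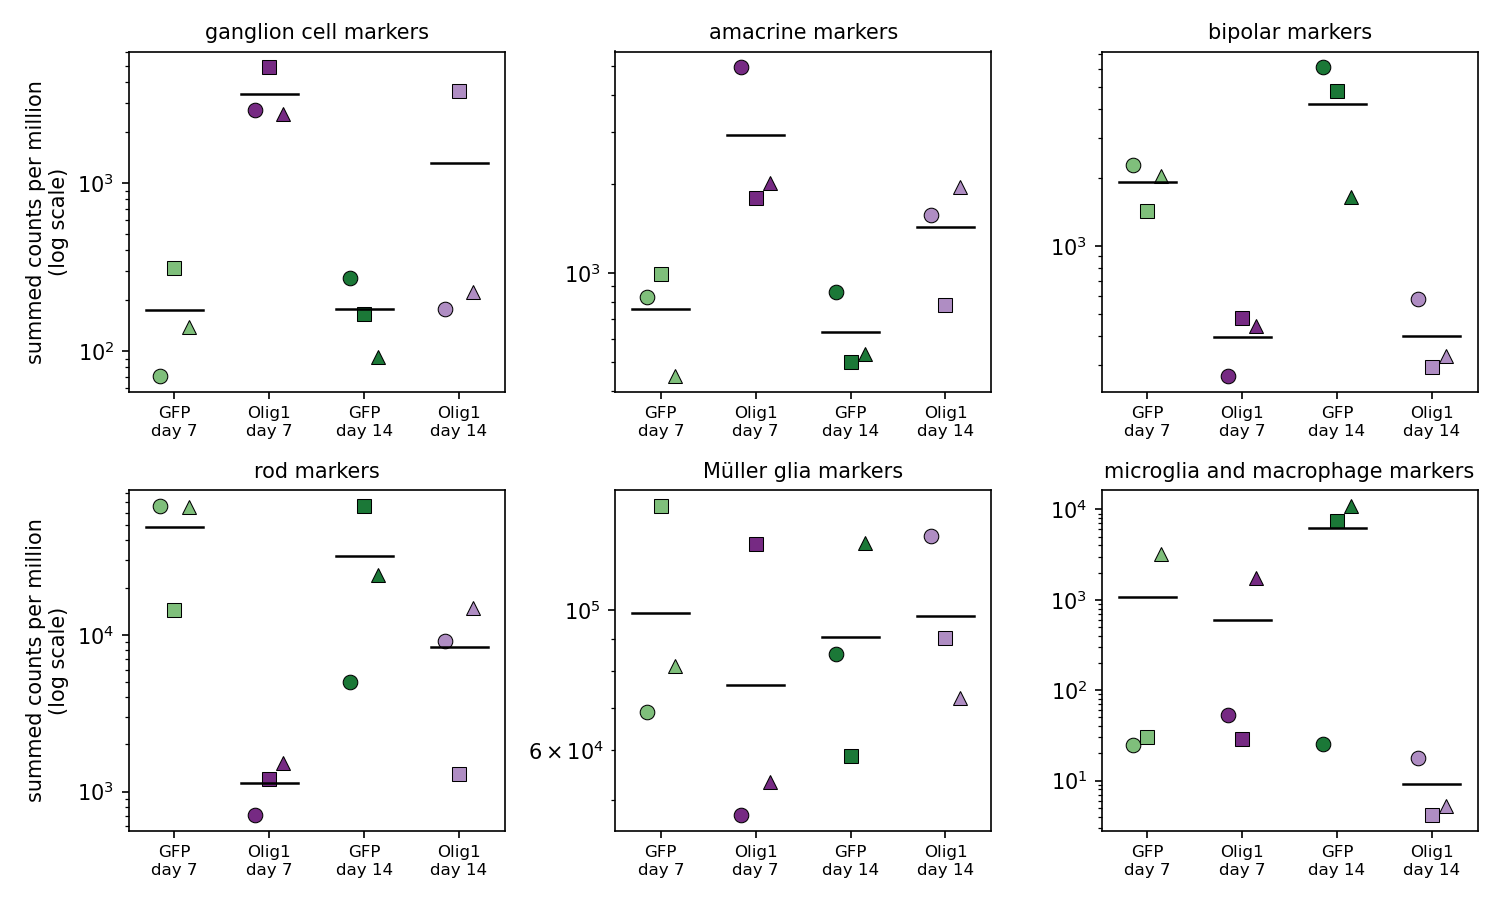
Summed marker level per library (CPM, log axis) for cell types of the retina, by group, with points for libraries and bars for group means. Ganglion cell markers average 3397 CPM in the Olig1 day 7 libraries and 174 CPM in the GFP day 7 libraries, and rod markers average 1143 and 48730 CPM.

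Which transcripts differed between pools given Olig1 and GFP at day 7 was the next question. Of 14985 genes tested 21 rose and 13 fell. Pde6g (ENSMUSG00000025386, chromosome 11, 120447605 to 120453500), a subunit of the rod phosphodiesterase, went from 6454 ± 2878 to 114 ± 36.9 CPM and fell by 5.61 ± 0.86 on the log2 scale (edgeR adjusted p = 0.0178). Trpm1 (ENSMUSG00000030523, chromosome 7, 64153835 to 64269775), the cation channel of ON bipolar cells, fell by 5.19 ± 0.66 (0.0113), and Sgk1, a serum- and glucocorticoid-regulated kinase, fell by 5.85 ± 0.80 (0.0113). The fall was -6.04 ± 0.96 for Nxnl2 and -5.39 ± 0.92 for Nxnl1, a pair of thioredoxin-like photoreceptor factors, -5.40 ± 0.87 for Guca1b, a guanylate cyclase activator, and -5.51 ± 0.96 for Cngb1, a subunit of the rod cyclic nucleotide-gated channel (adjusted p from 0.0178 to 0.0283). Cplx4, a complexin of ribbon synapses (-5.19 ± 0.86), Gzmm, a granzyme (-5.22 ± 0.99), and Rpgrip1, a protein of the photoreceptor cilium (-4.27 ± 0.82), fell as well, with adjusted p from 0.0204 to 0.0475. Gad1 (ENSMUSG00000070880, chromosome 2, 70553072 to 70602014), an enzyme of GABA synthesis, went from 0.503 ± 0.389 to 507 ± 463 CPM and rose by 10.20 ± 1.67 (adjusted p = 0.0204). Kif5a, a neuronal kinesin, rose by 8.76 ± 1.35, and Cplx2, a complexin of conventional synapses, by 8.41 ± 1.36 (both adjusted p = 0.0178). Gstm6, a glutathione transferase (10.63 ± 1.85), Scn2b, a sodium channel subunit (7.24 ± 1.29), Basp1, a growth cone protein (3.77 ± 0.72), and Mmp12, the macrophage elastase (10.31 ± 1.76), rose with adjusted p from 0.0283 to 0.0466.

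For genes with 1 to 3 counts in the GFP day 7 group, ratios of pooled counts with 95% counting intervals replace fitted folds. The ratio was 3665 (1014 to 30274) for C1ql2, a secreted synaptic protein of the complement C1q family (adjusted p = 0.0178), 4006 (1108 to 33084) for Nrip3 (0.0428), 2504 (693 to 20685) for Zcchc12 (0.0462) and 7208 (1293 to 284740) for Pcsk1, a prohormone convertase (0.0480). Olig1 day 7 replicate 2 carried much of 2 of these, with Pcsk1 at 422 CPM there against 25.0 and 23.3 CPM in the other Olig1 libraries and Nrip3 at 450 against 34.1 and 34.0 CPM. Without it the ratio was 1310 for Pcsk1 (adjusted p = 0.635) and 921 for Nrip3 (0.590). Without Olig1 day 7 replicate 1 the ratios of C1ql2, Nrip3, Zcchc12 and Pcsk1 were 2224, 6081, 1517 and 11150. Without GFP day 7 replicate 1 they were 2394, 2617, 1636 and 1569, and without replicate 2 they were 2428, 2654, 1659 and 4775. Without GFP day 7 replicate 3 they were 1672, 1827 and 1142 for C1ql2, Nrip3 and Zcchc12. The call was lost without any 1 of the GFP libraries for all 4 genes (adjusted p from 0.0681 to 0.361), for C1ql2 also without Olig1 day 7 replicate 1 (0.0508) and for Zcchc12 without any 1 of the Olig1 libraries (0.0509 to 0.120). Of the 34 genes called, 33 were protein coding, 8 belonged to a list fixed in advance, and in all 34 every library of one arm lay above every library of the other. Over all genes tested 18.4% had such arms, against 10% by chance, and 2090 genes had an unadjusted p under 0.05. Only Trpm1 kept its call whichever library was left out. The count of genes was 1 without GFP day 7 replicate 1, 9 without replicate 2 and 2 without replicate 3, and 18, 10 and 58 without Olig1 day 7 replicates 1, 2 and 3. DESeq2 gave 954 genes, limma voom 430 and the unfiltered edgeR test 218.

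By gene list at day 7, 18 of 48 lists were called by limma's camera, 11 higher and 7 lower. No list was called in any comparison with an estimated correlation, and fry also called 12 of the 18. Of 16 ganglion cell markers 15 had positive values, with a median of 5.01. None passed the test over all genes and 8 were higher adjusted over the list alone (camera adjusted p = 9.15e-11, adjusted p = 0.0581 with an estimated correlation). Slc17a6, the vesicular glutamate transporter of ganglion cells, stood at 0.0355 ± 0.0615 and 53.1 ± 34.3 CPM without passing (edgeR adjusted p = 0.179). All 15 rod genes had negative values, with a median of -5.12. Pde6g fell over all genes and 13 adjusted over the list alone (3.11e-22, adjusted p = 0.107 with an estimated correlation). The 15 bipolar genes had a median of -2.96, 1 fell over all genes and 7 adjusted over the list alone (1.62e-09, adjusted p = 0.0780 with an estimated correlation). The 9 cone genes had a median of -5.18, with 0 over all genes and 1 adjusted over the list alone (0.000253, adjusted p = 0.283 with an estimated correlation), and included Gnb3 at 1203 ± 494 and 35.2 ± 43.5 CPM. The 14 amacrine genes had a median of 2.52, with 2 higher over all genes, Gad1 and C1ql2, and 5 adjusted over the list alone (1.4e-07, adjusted p = 0.0581 with an estimated correlation). The 15 Müller glia genes had a median of -1.59, with 0 over all genes and 8 adjusted over the list alone (1.78e-07, adjusted p = 0.0780 with an estimated correlation), among them Car14 (-3.58 ± 0.75) and Aqp4 (-2.22 ± 0.55). Without Olig1 day 7 replicate 3 the bipolar median was -4.53.

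Injury, axon and metabolic lists followed at day 7, in libraries whose ganglion cell, rod and bipolar markers differed as given above. The 20 regeneration-associated genes, which axotomised neurons raise, had a median of 3.04. Basp1 rose over all genes and 9 rose adjusted over the list alone (camera adjusted p = 6.21e-08, adjusted p = 0.0581 with an estimated correlation). The 29 axon growth genes had a median of 1.55, with 0 over all genes and 10 adjusted over the list alone (7.93e-06, adjusted p = 0.126 with an estimated correlation), and Stmn3, a tubulin regulator, stood at 4.62 ± 0.93 and Marcks at 3.11 ± 0.72 without passing. The 31 synaptic genes had a median of 1.18, with 2 over all genes and 7 adjusted over the list alone (9.06e-06, adjusted p = 0.108 with an estimated correlation). The 23 voltage-gated channel genes had a median of 2.23, with 1 over all genes and 4 adjusted over the list alone (3.59e-06, adjusted p = 0.0815 with an estimated correlation). All 17 immediate early genes had positive values, with a median of 1.79, 0 over all genes and 1 adjusted over the list alone (6.03e-05, adjusted p = 0.236 with an estimated correlation). Nuclear genes of oxidative phosphorylation (73 genes, median 0.96, camera adjusted p = 7.93e-06), proteasome genes (31 genes, 0.83, 0.00128), cholesterol synthesis genes (21 genes, 1.21, 0.00705) and ribosomal protein genes (75 genes, 0.72, 0.0173) were also called higher. None of their members passed over all genes and only 1, of cholesterol synthesis, passed adjusted over the list alone; adjusted p = 0.311, 0.218, 0.311 and 0.744 with an estimated correlation. Astrocyte (-2.68, 0.0110), BMP and TGF-β (-1.91, 0.0173) and pericyte lists (-2.61, 0.0348) were called lower with 0 members over all genes and 0 adjusted over the list alone; adjusted p = 0.226, 0.311 and 0.159 with an estimated correlation. Among the members with the smallest p, none past the test, were Mvk (4.68 ± 1.45) of cholesterol synthesis, Uqcrq (2.50 ± 0.63) and Atp5g3 (1.72 ± 0.46) of oxidative phosphorylation, Psmc4 (2.46 ± 0.70) and Psmc1 (1.40 ± 0.47) of the proteasome, and Rpl6 (2.06 ± 0.72) and Rpl14 (1.71 ± 0.60) of the ribosome. Also among them were Nr4a2 (11.44 ± 2.41) among immediate early genes, Tgfb2 (from 273 ± 102 to 68.5 ± 43.5 CPM) and Bmpr1b (-6.87 ± 2.26) of the BMP and TGF-β list, Slc14a1 (-4.93 ± 1.94) and Aldh1l1 (-3.82 ± 2.20) of astrocytes, Vtn (-2.61 ± 1.25) and Pdgfrb (-2.79 ± 1.93) of pericytes, and Gngt2 (-3.90 ± 1.44) of cones. Medians moved by over 1.5 times without GFP day 7 replicate 1 (channels 3.41), GFP day 7 replicate 2 (BMP and TGF-β -0.81, pericyte -0.93), Olig1 day 7 replicate 2 (ribosome 0.09) and Olig1 day 7 replicate 3 (pericyte -6.13).

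Leaving out some single library removed 5 of the day 7 list calls. The astrocyte and BMP lists were lost without GFP day 7 replicate 2 (adjusted p = 0.0920 and 0.130) and cholesterol synthesis without GFP day 7 replicate 3 (0.107). The ribosomal list was lost without GFP day 7 replicate 1 (0.172) or 3 (0.127) or Olig1 day 7 replicate 2 (0.800), and the pericyte list without any GFP day 7 library or Olig1 day 7 replicate 1 (0.195 to 0.831).

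At day 14 the same question gave 6 genes, 3 higher and 3 lower of 14985. Ifit1 (ENSMUSG00000034459, chromosome 19, 34640871 to 34650009), an interferon-induced antiviral gene, went from 328 ± 244 CPM with GFP to 0.290 ± 0.297 CPM with Olig1 and fell by 10.23 ± 1.28 (edgeR adjusted p = 0.0106). Tgtp1, an interferon-induced GTPase, went from 80.1 ± 64.5 to 0.0839 ± 0.0752 CPM and fell by 9.96 ± 1.60 (0.0335), a value that may include reads of its near-identical paralog Tgtp2. Trpm1 went from 879 ± 564 to 48.7 ± 26.9 CPM and fell by 4.08 ± 0.63 (0.0335). Besides Olig1, Gad1 rose with a ratio of 5605 (1005 to 221424) on a single GFP count, and C1ql2 rose at least 755-fold over 0 counts (both 0.0335). The Gad1 ratio was 3597 and 1288 without GFP day 14 replicates 2 and 3 and 2617 and 9008 without Olig1 day 14 replicates 1 and 2. The C1ql2 bound was 484 without GFP day 14 replicate 2 and 1181 and 448 without Olig1 day 14 replicates 2 and 3. The arms did not overlap for 11.9% of genes, against 10% by chance, and 1563 genes had an unadjusted p under 0.05. No gene kept its call whichever library was left out. The count was 1, 2 and 3 without GFP day 14 replicates 1, 2 and 3, and 0 without Olig1 day 14 replicate 3, where Ifit1 had an adjusted p of 0.0859. It was 743 by DESeq2, 55 by limma voom, 23 without a filter, 2 with a stricter filter, 1 with a replicate block and 0 with only these groups in the fit. The count was also 0 without both GFP day 14 libraries that stood apart (replicates 1 and 3).

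By list at day 14, 9 of 48 were called, 4 higher and 5 lower, and fry called 1 of them. Without GFP day 14 replicates 1 and 3 together the amacrine (adjusted p = 0.168), axon growth (0.141) and antigen presentation calls (0.108) were lost and the subtype, cone and Müller glia lists newly passed. All 23 interferon response genes had negative values, with a median of -2.62. Ifit1 fell over all genes and 10 fell adjusted over the list alone (camera adjusted p = 4.3e-17, adjusted p = 0.0966 with an estimated correlation). The 11 genes of class I antigen presentation had a median of -1.68, with 0 over all genes and 3 adjusted over the list alone (0.000485, adjusted p = 0.382 with an estimated correlation), and H2-D1 went from 1733 ± 1169 to 352 ± 223 CPM and Psmb9, an immunoproteasome subunit, from 89.4 ± 50.8 to 14.7 ± 3.41 CPM without passing. All 17 microglia and macrophage genes had negative values, with a median of -10.17, or -10.26 with bounds for genes at 3 counts or fewer. None fell over all genes and 16 fell adjusted over the list alone (6.49e-11, adjusted p = 0.639 with an estimated correlation). P2ry12, a microglial purinergic receptor, went from 31.7 ± 18.3 to 0.0136 ± 0.0235 CPM and Tmem119 from 20.5 ± 18.9 to 0.0136 ± 0.0235 CPM, neither past the test. The bipolar list had a median of -2.93, with 1 over all genes and 8 adjusted over the list alone (7.54e-15, adjusted p = 0.0849 with an estimated correlation), and the rod list -1.79, with 0 over all genes and 0 adjusted over the list alone (6.19e-06, adjusted p = 0.740 with an estimated correlation). Pdc stood at -2.67 ± 1.02 and Sag, rod arrestin, at -2.66 ± 1.07. The rod median was -0.95 without GFP day 14 replicate 2. The cone list was not called (adjusted p = 0.0514), and the direction of its median rested on a single library, although the summed cone markers lay at 1177 CPM or more in every GFP library and at 760 CPM or less in every Olig1 library. The median of -1.84 became 1.90 without GFP day 14 replicate 2 (0.837) and -5.63 without Olig1 day 14 replicate 3 (0.00734), and it passed without GFP day 14 replicate 1 (0.000681) or 3 (0.0493). Of 21 cholesterol synthesis genes 20 had positive values, with a median of 1.72, 0 over all genes and 0 adjusted over the list alone (1.73e-05, adjusted p = 0.382 with an estimated correlation). Among them Fdft1, squalene synthase, stood at 2.03 ± 0.64 and Acat2 at 2.91 ± 0.99, and the median was 0.94 without Olig1 day 14 replicate 2.

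Ganglion cell, amacrine and axon lists at day 14 had smaller medians than at day 7. Ganglion cell markers had a median of 2.66, or 2.53 with bounds, with 0 over all genes and 2 adjusted over the list alone (camera adjusted p = 0.000519, adjusted p = 0.450 with an estimated correlation). Ebf3, a transcription factor of ganglion cells, went from 0.0121 ± 0.0209 to 46.6 ± 77.9 CPM without passing. Amacrine markers had a median of 0.93, with 2 over all genes and 2 adjusted over the list alone (0.00724, adjusted p = 0.384 with an estimated correlation), and axon growth genes 0.99, with 0 over all genes and 0 adjusted over the list alone (0.0458, adjusted p = 0.740 with an estimated correlation). Map1b, a microtubule-associated protein, stood at 1.81 ± 0.82 and Robo1, a guidance receptor, at 0 and 1.59 ± 2.10 CPM. The ganglion cell call was lost without Olig1 day 14 replicate 2 (adjusted p = 0.0741) and the amacrine call without Olig1 day 14 replicate 1 (0.0717). The axon growth call was lost without GFP day 14 replicate 2 (0.101) or 3 (0.145) or Olig1 day 14 replicate 2 (0.359). Without Olig1 day 14 replicate 2 the ganglion cell median was 1.49 and the axon growth median 0.50, without GFP day 14 replicate 3 the axon growth median was 0.61, and without Olig1 day 14 replicate 3 the amacrine median was 0.45.

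The mean effect of Olig1 over both days, with 6 libraries an arm, took in 98 genes, 57 higher and 41 lower. A call on the mean does not require the same effect at each day. Ifit1 stood at -1.08 ± 0.87 at day 7 and -10.23 ± 1.28 at day 14, and Cplx2 at 8.41 ± 1.36 and -0.98 ± 1.00. The fall was -4.63 ± 0.45 for Trpm1 (edgeR adjusted p = 0.000261), -4.83 ± 0.64 for Nxnl1 (0.00293) and -4.91 ± 0.85 for Gnb3, the G protein β subunit of cones and ON bipolar cells (0.0291). Of the interferon genes, Ifit1 (-5.65 ± 0.75, 0.00293) and Ifit3 (-4.46 ± 0.89, 0.0445) fell. Sebox, a homeobox gene (-7.17 ± 1.13), Slc1a7, a glutamate transporter (-6.99 ± 1.44), Kcne2, a potassium channel subunit (-8.13 ± 1.73), and Cnmd, chondromodulin (-6.10 ± 1.31), fell with adjusted p from 0.0135 to 0.0466. Rtn4rl2, a Nogo receptor homolog and the 1 called member of the brakes on axon regrowth, fell from 18.7 ± 9.03 to 0.454 ± 0.0482 CPM at day 7 and from 10.9 ± 6.36 to 0 CPM at day 14 (0.0327). Cep112 fell from 30.0 ± 15.8 to 0.344 ± 0.596 CPM and from 17.2 ± 6.76 to 0 CPM (0.0331). Gad1 rose by 11.06 ± 1.25 (0.000996), and Tac2, the neurokinin B precursor, by 11.41 ± 2.10 (0.0376). Over 12 omissions of a library, the call was lost in 11 for Rtn4rl2 (highest adjusted p = 0.117), Kcne2 and Ifit3. It was lost in 10 for Slc1a7 and Tac2, in 9 for Cep112 and Cnmd, in 7 for Gnb3 and in 5 for Sebox. Galanin (Gal) rose at least 1863-fold, Kitl, the KIT ligand, at least 730-fold and Setmar at least 456-fold over 0 counts in the GFP libraries (adjusted p from 0.0326 to 0.0473). Gal rested on Olig1 day 14 replicate 2, with 162 CPM against at most 26.0 CPM in the other libraries. Without it the bound was 357 and the call was lost (0.155), as in 9 of 12 omissions. The Kitl bound was 457 without Olig1 day 7 replicate 1, and the Kitl and Setmar calls were lost in 8 and 12 omissions (highest adjusted p = 0.0917 and 0.134). The ratio was 4827 (1336 to 39861) for C1ql2, 3032 (839 to 25041) for Zcchc12, 4027 (722 to 159113) for Tbx20 and 1429 (395 to 11806) for Tmem178 (adjusted p from 0.000996 to 0.0326). Without GFP day 7 replicate 3 the ratios were 2799 for C1ql2, 1758 for Zcchc12 and 829 for Tmem178, and without Olig1 day 7 replicate 1 they were 2964 for C1ql2 and 1704 for Zcchc12. The Tbx20 ratio was 1060 without GFP day 14 replicate 2 and 1259 without Olig1 day 14 replicate 2. The Tbx20 and Tmem178 calls were lost in 8 and 9 omissions (highest adjusted p = 0.129 and 0.0921).

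Of these 98 genes, 94 were protein coding and 26 belonged to a list fixed in advance. In 67 the arms did not overlap within either day, which held for 2.28% of all genes against 0.5% by chance, and 2230 genes had an unadjusted p under 0.05. The call held whichever library was left out for 19 genes, among them Olig1, Trpm1, Gad1, C1ql2, Nxnl1, Ifit1 and Zcchc12. The count was 26, 32 and 27 without GFP day 7 replicates 1, 2 and 3, and 45, 31 and 133 without Olig1 day 7 replicates 1, 2 and 3. It was 27 and 41 without GFP day 14 replicates 2 and 3, 49 and 63 without Olig1 day 14 replicates 2 and 3, and 43 without GFP day 14 replicates 1 and 3 together. DESeq2 gave 1153 genes, limma voom 460 and the unfiltered test 401.

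By list over both days, 19 of 48 were called, 11 higher and 8 lower, 12 of them also by fry. Ganglion cell markers had a median of 3.57, with Slc17a6 higher over all genes (ratio 1957, 541 to 16170, edgeR adjusted p = 0.0326) and 12 adjusted over the list alone (camera adjusted p = 1.25e-11, adjusted p = 0.112 with an estimated correlation). Subtype markers had a median of 1.56, with Cartpt, a neuropeptide precursor, higher by 9.72 ± 1.63 and 4 higher and 1 lower adjusted over the list alone (0.0207, adjusted p = 0.307 with an estimated correlation). Rod genes had a median of -3.60, with 5 lower over all genes and 15 adjusted over the list alone (1.05e-21, adjusted p = 0.114 with an estimated correlation). They included Gnat1, rod transducin (-4.00 ± 0.73), Pdc, phosducin (-4.08 ± 0.77), Rcvrn, recoverin (-3.61 ± 0.71), and Pde6g (-3.60 ± 0.55). Bipolar genes had a median of -3.03, with 2 lower over all genes, Trpm1 and Cabp5 (-3.03 ± 0.64), and 11 adjusted over the list alone (6.26e-19, adjusted p = 0.0542 with an estimated correlation). Cone genes had a median of -3.55, with 1 lower over all genes and 4 adjusted over the list alone (0.000106, adjusted p = 0.307 with an estimated correlation). Amacrine genes had a median of 1.93, with 3 higher over all genes, C1ql2, Gad1 and Tfap2b (1.92 ± 0.39), and 4 adjusted over the list alone (9.11e-08, adjusted p = 0.0958 with an estimated correlation). Müller glia (-0.69, 0.00744), astrocyte (-1.46, 0.0216) and microglia lists (-5.52, 3.93e-05) were called lower, with 0 members over all genes and 1, 1 and 5 adjusted over the list alone; adjusted p = 0.307, 0.307 and 0.529 with an estimated correlation. Clu, clusterin, a Müller glia marker, stood at -0.95 ± 0.33 and Slc14a1, an astrocyte marker, at -4.48 ± 1.34, as did Car14 (-1.83 ± 0.49), Aldh1l1 (-2.15 ± 1.45), Tmem119 (-6.60 ± 1.98) and P2ry12 (-6.02 ± 1.98), none past the test. The Slc17a6 ratio was 1118 without GFP day 7 replicate 1 and 1128 without Olig1 day 7 replicate 1, and its call was lost in 8 of 12 omissions (highest adjusted p = 0.104). The subtype median ran from 0.79 without Olig1 day 7 replicate 2 to 4.64 without GFP day 14 replicate 3. The cone median was -1.43 without GFP day 14 replicate 2 and -5.34 without Olig1 day 14 replicate 3. Without GFP day 14 replicate 1 the Müller and astrocyte medians were -0.41 and -0.76, and without GFP day 7 replicate 3 the microglia median was -1.03.

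Among function lists over both days, regeneration-associated genes had a median of 1.88, with 4 higher over all genes and 8 adjusted over the list alone (camera adjusted p = 3.17e-05, adjusted p = 0.114 with an estimated correlation). The 4 were Gal, Basp1 (2.49 ± 0.48), Stmn4 (2.84 ± 0.59) and Sprr1a, a small proline-rich protein raised in axotomised neurons (ratio 1723, 589 to 8357). Axon growth genes had a median of 1.01, with Stmn3 (3.14 ± 0.61) and Marcks (2.29 ± 0.49) higher over all genes and 11 adjusted over the list alone (7.65e-06, adjusted p = 0.148 with an estimated correlation). Synaptic genes had a median of 0.73, with 2 higher over all genes, among them Cplx2 (3.72 ± 0.78), and 8 adjusted over the list alone (6.1e-05, adjusted p = 0.151 with an estimated correlation). Voltage-gated channel genes had a median of 1.83, with Scn2b (4.25 ± 0.79) higher over all genes and 5 adjusted over the list alone (1.05e-05, adjusted p = 0.114 with an estimated correlation). Immediate early genes had a median of 1.29, with Nr4a2, a nuclear receptor (9.77 ± 1.68), higher over all genes and 2 adjusted over the list alone (0.00114, adjusted p = 0.334 with an estimated correlation). Interferon response genes had a median of -1.84, with 2 lower over all genes and 7 adjusted over the list alone (4.6e-11, adjusted p = 0.114 with an estimated correlation). Cholesterol synthesis (1.62, 7.68e-06), oxidative phosphorylation (0.59, 0.00379) and proteasome genes (0.63, 0.00744) were called higher and class I antigen presentation lower (-0.84, 0.0106), with 0 members over all genes and 2, of cholesterol synthesis, adjusted over the list alone. With an estimated correlation their adjusted p = 0.161, 0.585, 0.321 and 0.321. Among the members of these lists with the smallest p, none past the test, were Fdft1 (1.62 ± 0.44), Cox7b (1.51 ± 0.47), Atp5j (1.08 ± 0.33), Psmb2 (1.22 ± 0.41), Psmb6 (1.05 ± 0.36), Psmb10 (-1.35 ± 0.47) and Psmb8 (-1.16 ± 0.48). Medians with bounds equalled the fitted medians to 2 decimals. The Sprr1a ratio was 4448 without GFP day 7 replicate 2 and 559 without Olig1 day 7 replicate 1, and its call was lost in 8 of 12 omissions (highest adjusted p = 0.133). The regeneration median was 0.81 without Olig1 day 7 replicate 3 and the antigen presentation median -0.46 without GFP day 14 replicate 3. Without GFP day 14 replicate 2 the channel and synaptic medians were 3.00 and 1.39, and without GFP day 7 replicate 3 the synaptic median was 1.15.

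Without GFP day 14 replicates 1 and 3 together the calls over both days for Müller glia (adjusted p = 0.101), astrocytes (0.0748) and antigen presentation (0.0765) were lost. The microglia call over both days was lost without GFP day 7 replicate 3 (adjusted p = 0.293), the Müller call without GFP day 14 replicate 1 (0.0656) and the proteasome call without Olig1 day 14 replicate 2 (0.0554). The astrocyte call was lost without GFP day 7 replicate 2 (0.0958) or GFP day 14 replicate 1 (0.114). The subtype call was lost without GFP day 7 replicate 1 (0.0903), Olig1 day 7 replicate 3 (0.103) or GFP day 14 replicate 2 (0.176).

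**Figure D3:**
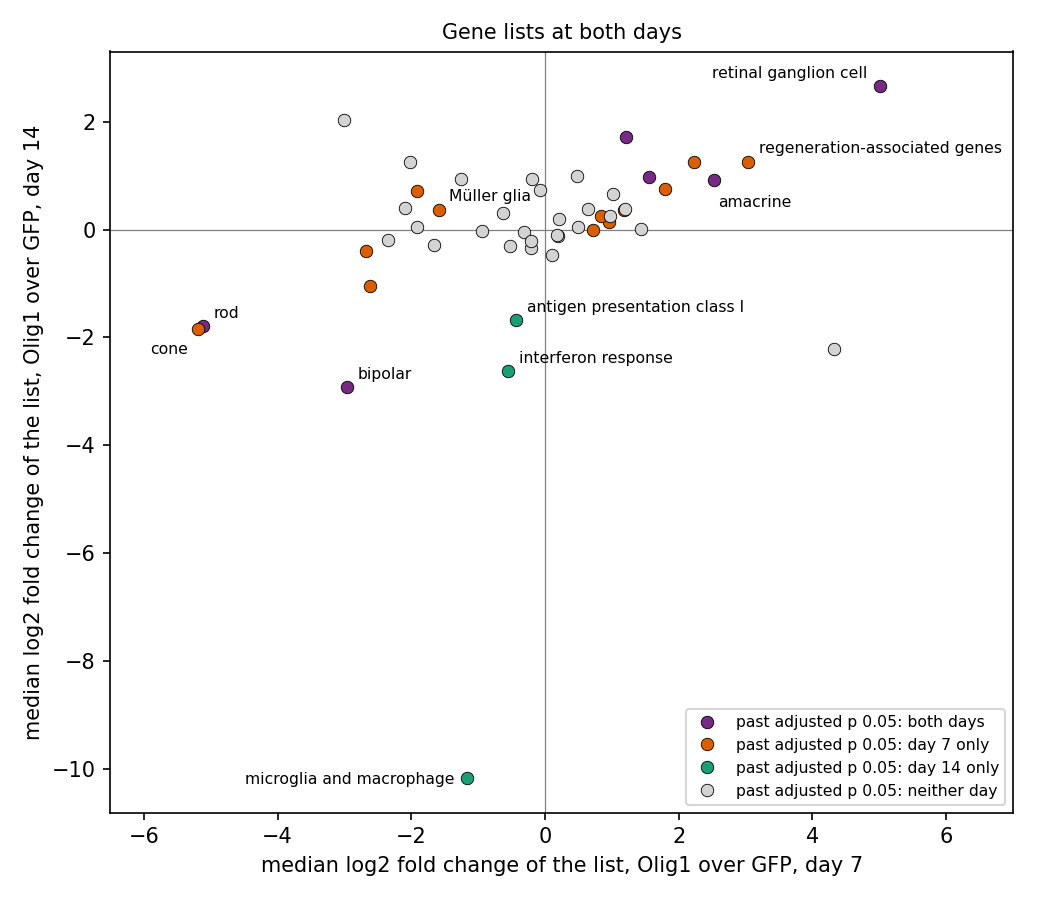
Median log2 fold change of Olig1 over GFP for each tested gene list at day 7 and day 14. Colours mark lists called by camera at both days, at day 7 only or at day 14 only, and light grey marks lists called at neither. At day 7 the ganglion cell list is at 5.01 and the rod list at -5.12, and at day 14 the interferon list is at -2.62.

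A panel of injury and regeneration genes, fixed in advance, was followed over both days, since ganglion cell survival and axon regrowth frame studies of nerve crush. Of the panel, Olig1, Slc17a6 and Sprr1a passed in a comparison of Olig1 with GFP, and Sox11 between the days with Olig1. Gap43, a growth cone protein, went from 0.728 ± 0.635 to 631 ± 470 CPM at day 7 and from 14.6 ± 18.6 to 171 ± 208 CPM at day 14 (edgeR adjusted p = 0.147 and 0.535). Jun, the transcription factor of the axon injury response, stood at 3.99 ± 1.48 and 1.27 ± 1.33, Ddit3, a stress-induced pro-apoptotic factor, at 3.97 ± 0.92 and 0.26 ± 0.81, and Nefl, the neurofilament light chain, at 3.97 ± 1.62 and 2.78 ± 1.54. Sox11 went from 4.60 ± 6.27 to 161 ± 101 CPM at day 7 and from 0.685 ± 0.295 to 0 CPM at day 14. Bbc3, the pro-apoptotic PUMA, went from 0.0355 ± 0.0615 to 24.9 ± 26.3 CPM and from 0.274 ± 0.475 to 0 CPM. The day 7 and day 14 values were 2.24 ± 1.45 and 4.50 ± 1.60 for Klf7, 0.28 ± 1.44 and 1.34 ± 1.47 for Klf6, -0.73 ± 1.02 and 1.52 ± 1.04 for Klf9, 1.78 ± 1.97 and -1.12 ± 2.00 for Atf3, and 3.28 ± 2.27 and 0.50 ± 2.09 for Socs3. They were 0.28 ± 0.91 and -0.26 ± 0.91 for Stat3, 0.48 ± 0.98 and -1.60 ± 1.00 for Bdnf, and -1.72 ± 1.10 and 0.95 ± 1.08 for Ntrk2. The ganglion cell markers Thy1, which encodes the CD90 antigen of the beads (4.79 ± 1.58 and -0.06 ± 1.35), and Rbpms (3.58 ± 2.26 and 3.07 ± 2.22), and the glial genes Mbp (-2.09 ± 2.60 and 1.43 ± 2.55) and Gfap (-3.51 ± 2.35 and 0.11 ± 2.13) did not pass. Klf4 and Pou4f1 were too low to test.

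Whether the effect of Olig1 differed between the days was tested by an interaction. No gene passed in edgeR (smallest adjusted p = 0.142 for Ifit1), while 1484 had an unadjusted p under 0.05 and DESeq2, limma voom and the unfiltered test gave 527, 0 and 40 genes. The smallest p belonged to Ifit1 (-9.15 ± 1.42), Cplx2 (-9.39 ± 1.63), Gstm6 (-10.74 ± 2.10), Tgtp1 (-8.52 ± 1.77) and Sox11 on the lower side. On the higher side they belonged to Sgk1 (5.40 ± 0.98), Nbl1, a BMP antagonist (4.18 ± 0.92), Mfge8 (3.76 ± 0.83), Wscd1 and Sod3, an extracellular superoxide dismutase. Wscd1 stood at 23.3, 3.73, 0.0362 and 36.4 CPM and Sod3 at 71.8, 0.314, 0 and 18.6 CPM in the 4 groups. Between the days' calls, C1ql2, Gad1 and Olig1 were higher in both (3 genes, 0.0042 expected by independence) and Trpm1 lower in both (1 gene, 0.0026 expected). With the stricter filter only Olig1 was called in both, and with a replicate block no gene was. Of the 34 day 7 calls 30 had the same sign at day 14, and all 6 day 14 calls had the same sign at day 7. Across genes, which are not independent replicates, the 2 fold changes correlated with a Pearson r of 0.142 and a Spearman coefficient of 0.133.

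Lists differed between the days in 11 of 48 cases by camera, 1 of them, Müller glia, also by fry. The effect at day 14 minus that at day 7 had a median of 3.02 for rod genes (adjusted p = 1.78e-07, adjusted p = 0.447 with an estimated correlation), 1.90 for Müller glia (6.65e-07, adjusted p = 0.361 with an estimated correlation) and 3.86 for oligodendrocyte lineage genes without Olig1 (4 genes, 0.0485, adjusted p = 0.393 with an estimated correlation). It was -1.29 for ganglion cell markers (0.0215, adjusted p = 0.447 with an estimated correlation), -2.64 for regeneration-associated genes (0.000854, adjusted p = 0.393 with it), -1.97 for the interferon response (9.68e-07, adjusted p = 0.393 with it) and -9.28 for microglia (1.46e-08, adjusted p = 0.447 with it). It was -0.93 for synaptic genes (0.0169), -1.83 for voltage-gated channels (0.0313), -0.78 for nuclear oxidative phosphorylation (0.000635) and 0.81 for mitochondrially encoded genes (0.0200). With an estimated correlation their adjusted p = 0.447, 0.447, 0.484 and 0.552. Over all genes no member passed. Adjusted over the list alone, 6 Müller glia genes, 1 rod gene and 2 oligodendrocyte lineage genes had a higher effect at day 14, and 2 regeneration, 1 synaptic, 3 channel and 2 interferon genes a lower one. The calls for rod, Müller glia, microglia, regeneration, oxidative phosphorylation and interferon lists held whichever library was left out. Without GFP day 14 replicates 1 and 3 together the interferon (0.417), ganglion cell (0.209) and oligodendrocyte calls (0.160) were lost. The count of lists was 7 without Olig1 day 14 replicate 1. The oligodendrocyte call was lost in all 12 omissions (0.0862 to 0.250). The ganglion cell call was lost in 5 (0.0545 without GFP day 14 replicate 1 to 0.259 without Olig1 day 14 replicate 1), the channel call in 7 (0.0518 without GFP day 14 replicate 1 to 0.245 without GFP day 7 replicate 2), the synaptic call in 4 (0.0531 without Olig1 day 7 replicate 1 to 0.0896 without GFP day 7 replicate 2) and the mitochondrial call in 2 (0.0946 without Olig1 day 14 replicate 1, 0.0960 without Olig1 day 7 replicate 1).

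Medians of the difference between the days also moved for many of these lists when a library was left out. The ganglion cell median of -1.29 turned to 0.21 without GFP day 14 replicate 3 and to 0.11 without Olig1 day 7 replicate 2, so its direction is not settled. It was -0.49 without GFP day 14 replicate 2, -0.66 and -3.33 without Olig1 day 14 replicates 1 and 2, and -3.16 and -2.90 without GFP day 7 replicates 2 and 3. The regeneration median of -2.64 was -1.27 and -0.68 without GFP day 14 replicates 1 and 3. The microglia median of -9.28 was -18.47 without GFP day 7 replicate 3 and -4.88 without Olig1 day 7 replicate 3. The rod median of 3.02 was 1.80 without Olig1 day 14 replicate 3, the interferon median of -1.97 was -3.01 without GFP day 7 replicate 2, and the synaptic median of -0.93 was -1.44 without Olig1 day 14 replicate 1. The channel median of -1.83 was -0.99 without GFP day 14 replicate 1 and -1.11 without Olig1 day 7 replicate 2. The mitochondrial median of 0.81 was 0.54 without Olig1 day 14 replicate 1 and 0.34 and 1.46 without Olig1 day 7 replicates 1 and 3, and that of oxidative phosphorylation, -0.78, was -0.50 without Olig1 day 7 replicate 3.

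The course after injury in GFP pools was compared between day 14 and day 7, with positive values higher at day 14. CT010467.1 lay at 6776 CPM or more in every day 7 library of either virus. In every day 14 library it lay at 1367 CPM or less. The labels do not assign libraries to batches, so a batch difference between the days cannot be told from the course after injury. Any effect of the time since virus injection was not tested. No gene passed in edgeR (smallest adjusted p = 0.340), 1540 genes had an unadjusted p under 0.05, and DESeq2, limma voom and the unfiltered test gave 646, 17 and 13 genes. The smallest p on the higher side belonged to Actr2, an actin nucleator (3.40 ± 0.63), Mrpl58 (3.35 ± 0.66), Srsf2, a splicing factor (3.23 ± 0.65), Dpysl2 (2.89 ± 0.60) and H3f3b, a histone (1.77 ± 0.36). On the lower side they belonged to CT010467.1, an RNA resembling ribosomal RNA (-3.68 ± 0.62), and Shank1, a postsynaptic scaffold (-3.24 ± 0.61), and to Chl1, Nudcd1 and Ret, with 18.9 ± 11.1, 26.3 ± 25.3 and 12.4 ± 7.16 CPM at day 7 and 0 counts at day 14. By camera, 6 of 48 lists were called, with 0 members over all genes and, adjusted over the list alone, 2 of glycolysis and 2 of the proteasome. Oxidative phosphorylation (0.87, adjusted p = 4e-12), proteasome (0.81, 3.39e-05), glycolysis (0.40, 0.00579), bipolar (1.02, 0.0275) and microglia lists (3.03, 3.39e-05) were higher and Müller glia lower (-0.91, 0.0228). With an estimated correlation their adjusted p = 0.479, 0.479, 0.392, 0.593, 0.593 and 0.593, and fry called glycolysis alone. The median over all genes was -0.14 with TMM and -0.25 with DESeq2 size factors. The bipolar call was lost without GFP day 14 replicate 1 (0.329) or 2 (0.0587) or GFP day 7 replicate 2 (0.186) or 3 (0.0555). The Müller call was lost without GFP day 14 replicate 2 (0.289) or 3 (0.0702) or GFP day 7 replicate 2 (0.169). Without GFP day 14 replicates 1 and 3 together the bipolar (0.149) and glycolysis calls (0.0642) were lost. The Müller median was -1.45 without GFP day 14 replicate 1, and the microglia median was 1.99 without GFP day 14 replicate 3 and 12.26 without GFP day 7 replicate 3.

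In pools given Olig1, 5 genes passed between day 14 and day 7, 1 higher and 4 lower, with 1766 at an unadjusted p under 0.05. Batch cannot be told from day here either. Bsg (ENSMUSG00000023175, chromosome 10, 79704491 to 79711969), basigin, a partner of lactate transporters, rose by 2.91 ± 0.41 from 1347 ± 179 to 9604 ± 4445 CPM (edgeR adjusted p = 0.0270). Shank1 (-4.48 ± 0.64, 0.0270), CT010467.1 (-4.10 ± 0.63, from 15468 ± 10378 to 1010 ± 309 CPM, 0.0282) and Ifit1 (-7.40 ± 1.15, 0.0282) fell. Sox11, a transcription factor of growing neurons, fell at least 3369-fold to 0 counts (0.0282), or at least 2076-fold without Olig1 day 14 replicate 2 (0.166). Lists called higher were rod (2.46, camera adjusted p = 6.64e-07), horizontal (1.50, 0.0405), Müller glia (1.31, 4.97e-05) and mitochondrially encoded genes (0.61, 0.00512). Lists called lower were ganglion cell (-2.19, 0.0011), amacrine (-2.06, 0.0157), microglia (-6.66, or -6.59 with bounds, 0.000632), erythrocyte (-7.89, 0.0101), regeneration (-2.06, 4.97e-06), immediate early (-2.29, 4.15e-06), interferon (-1.28, 0.00027), class I antigen presentation (-1.67, 0.0195), ribosome (-0.87, 0.000632), synaptic (-1.04, 0.0352), voltage-gated channels (-0.73, 0.0145) and DLK and JNK signalling (-0.86, 0.0289). Their adjusted p ranged from 0.424 to 0.565 with an estimated correlation, and fry called none. Over all genes the members that fell were Sox11 and Ifit1. Adjusted over the list alone, 5 rod, 4 Müller glia, 3 mitochondrially encoded and 1 horizontal gene rose and 5 regeneration, 4 immediate early, 4 erythrocyte, 3 antigen presentation and 2 interferon genes and 1 each of the synaptic, channel and DLK and JNK lists fell. The count of genes was 2 and 10 without Olig1 day 7 replicates 1 and 3, and 0, 1 and 0 without Olig1 day 14 replicates 1, 2 and 3. It was 626 by DESeq2, 313 by limma voom, 59 unfiltered, 2 with a stricter filter and 0 with DESeq2 size factors, which moved the median over all genes from -0.01 to -0.19, or with only these groups in the fit.

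Most list calls for the course with Olig1 were lost when some single library was left out, several of them in more than 1 omission. Only those for rods, Müller glia, regeneration, immediate early and interferon genes held in every omission. Without Olig1 day 14 replicate 1 the ganglion cell (adjusted p = 0.122), horizontal (0.136), erythrocyte (0.140), antigen presentation (0.122), synaptic (0.121), channel (0.0977), mitochondrial (0.0740) and DLK and JNK calls (0.121) were lost, and 10 lists were called. Without Olig1 day 14 replicate 2 the amacrine call was lost (0.0965), and without replicate 3 the ribosome call (0.0906). Without Olig1 day 7 replicate 3 the microglia call was lost (0.0982). The remaining losses were again of these lists, with adjusted p from 0.0647 (ribosome, without Olig1 day 7 replicate 2) to 0.160 (antigen presentation, without Olig1 day 7 replicate 3).

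Medians of the course with Olig1 also moved by over 1.5 times when a library was left out. Without Olig1 day 7 replicate 1 they were -0.81 for antigen presentation, -0.56 for DLK and JNK signalling, 4.43 for horizontal cells, 0.14 for mitochondrially encoded and -0.39 for synaptic genes. Without Olig1 day 7 replicate 2 they were -0.41 for the ribosome, -2.65 for erythrocytes, 3.68 for horizontal cells and -1.36 for ganglion cells. Without Olig1 day 7 replicate 3 they were -1.09 for antigen presentation, -0.31 for DLK and JNK signalling, 6.64 for horizontal cells, -0.68 for interferon genes, -2.03 for microglia and 0.98 for mitochondrially encoded genes. Without Olig1 day 14 replicate 1 they were 0.24 for mitochondrially encoded genes, -1.44 for ganglion cells and -1.19 for channels. Without Olig1 day 14 replicate 2 they were 4.20 for horizontal cells, -3.89 for ganglion cells and -1.38 for channels, and without replicate 3 they were 4.31 for horizontal cells, 1.43 for rods and -1.20 for channels.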

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

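The tests of library depth and of plasma cell genes were written down before their results were seen; all other explanations, and the regrouping of libraries, were chosen only after the result was seen. The interaction test set apart 11 gene lists whose Olig1 effect differed between day 14 and day 7 by camera. The oligodendrocyte call was lost in all 12 omissions of a library. None of the 11 lists was called with an estimated correlation, and fry called 1 of them. Their medians of the effect at day 14 minus that at day 7 were -1.29 for ganglion cell markers (0.21 without GFP day 14 replicate 3 and 0.11 without Olig1 day 7 replicate 2), 3.02 for rods, 1.90 for Müller glia, -9.28 for microglia and macrophages and 3.86 for the oligodendrocyte lineage. They were -2.64 for regeneration-associated genes, -0.93 for synaptic genes, -1.83 for voltage-gated channels, -0.78 for nuclear oxidative phosphorylation, 0.81 for mitochondrially encoded genes and -1.97 for the interferon response. Among 60 regroupings that kept the group sizes, 12 gave at least 11 lists and the highest gave 21, so chance is not excluded for these 11. All 60 gave at least the 0 genes of the interaction, and the highest gave 1.

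The regrouping also bears on the other counts. For the mean of both days, 1 of 60 regroupings, the real one, reached 98 genes and the highest other reached 1. Chance is thus unlikely for that count, but 60 draws cannot exclude it. Regrouped labels also mix the viruses within a group, which widens the fitted spread. The count itself ran from 26 to 133 over omissions of a library. For lists 1 of 60, the real one, reached 19 and the highest other reached 18. The real count itself was 18 without GFP day 7 replicate 3 or GFP day 14 replicate 1 or 2, 17 without GFP day 14 replicates 1 and 3 together and 0 with an estimated correlation, so chance is not firmly excluded for the lists. At each single day and between days only 10 splits exist, which are too few to exclude chance. The real and highest other counts of genes were 34 and 0 at day 7 (1 of 10), 6 and 0 at day 14 (1 of 10), 0 and 1 for GFP day 14 against day 7 (10 of 10) and 5 and 0 for Olig1 day 14 against day 7 (1 of 10). For lists they were 18 and 12 (1 of 10), 9 and 6 (1 of 10), 6 and 7 (4 of 10) and 16 and 13 (1 of 10).

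The first pattern weighed is that camera called the ganglion cell and amacrine lists higher, and the rod and bipolar lists lower, with Olig1 at day 7. None of these calls held with an estimated correlation, and few of the members passed over all genes. If the GFP pools held a smaller share of ganglion cells, with every other cell type filling the rest, amacrine genes should fall with Olig1. Their median was 2.52 (2.17 to 3.20 over omissions of a library), against -5.12 for rods. The amacrine rise is part of the pattern and was known beforehand, so this speaks only against that simple mix. Whether the Olig1 pools were richer in both ganglion and amacrine cells was not tested. If rod RNA had entered the GFP pools as 1 mixture, rod genes could be expected to share 1 fold change. Their SD of 1.21 was matched by 16.4% of random gene sets of like level, which leaves this open. Depth may be set aside, since with all libraries thinned to 12534515 counts the rod median was -5.04. An effect of Olig1 on the picked cells remains untested, because the virus and the mix of cell types differed together.

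The second pattern is that camera called the interferon response list lower with Olig1 at day 14. Of its members only Ifit1 passed over all genes, and the list call did not hold with an estimated correlation. RNA of microglia or macrophages could not account for GFP replicate 1, which held 9228 CPM of interferon genes with 25.3 CPM of microglia markers, where 6938 CPM would be needed at 1.33, the highest ratio of interferon to microglia sums among libraries rich in microglia markers. In GFP replicates 2 and 3 microglia markers reached at least 7489 CPM and the group differed in both, so microglial RNA is possible there and could not be told from the group. The bead and picking steps would be thought to remove microglia, and how their RNA would have entered was not tested. Depth is set aside, with a median of -2.67 after thinning. A response of the picked cells to the vector remains untested, since no uninjected group was analysed here.

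The third pattern is the immunoglobulin RNA at 15.3% of the counts of GFP day 14 replicate 3. If it came from an antibody-secreting cell, other plasma cell genes might be highest in that library too, and 5 of 14 listed genes were. Of these Mzb1 (34.6 CPM), Derl3 (10.9 CPM), Irf4 (4.26 CPM) and Cd79a (7.39 CPM) had a median of at most 1 CPM elsewhere, while Xbp1 (269 CPM) is among 5 of the 14 whose median elsewhere passed 1 CPM. Irf4 and Cd79a had 0 CPM in every other library, while Tnfrsf17 and Pou2af1 had 0 counts. The bead and picking steps would be thought to remove such cells. This library also held 10985 CPM of microglia and macrophage markers, so those steps are no ground against such a source. With 5 of 14 genes highest in this library, the listed genes do not decide the source. The design gives no group for a biological explanation, and none was tested.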

How the results depend on the processing

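No named gene or Olig1 value that passed in the planned test or in an alternative had opposite directions in the 2, and no list did by the direction camera gives. By its median the ganglion cell list of the interaction (-1.29) turned to 0.21 without GFP day 14 replicate 3 and to 0.11 without Olig1 day 7 replicate 2. Counts of genes depended strongly on the tool, filter and library set, and the cause was not tested unless stated. In the order day 7, day 14, mean of both days, interaction, GFP day 14 against 7 and Olig1 day 14 against 7, the counts were 34, 6, 98, 0, 0 and 5. DESeq2 gave 954, 743, 1153, 527, 646 and 626, and in the simulated data it made 155 to 244 false calls a comparison. Limma voom gave 430, 55 and 460 for the Olig1 effects, 0 for the interaction and 17 and 313 for the courses after injury. Without a filter the counts were 218, 23, 401, 40, 13 and 59. The stricter filter gave 2 at day 14 and 2 for the course with Olig1. DESeq2 size factors gave 0 for the course with Olig1. A replicate block gave 1 at day 14, 64 for the mean and 1 for the interaction. The labels do not say whether a replicate number marks a pair or a batch. Deviations of libraries with the same number correlated at -0.0507 to 0.0441 across genes (6 pairs), and each library correlated best with its own number at day 7 and none did at day 14. With only the groups compared in the fit, which leaves fewer libraries for the spread, the count was 0 at day 14 and 0 for the course with Olig1. Without both GFP day 14 libraries that stood apart, an alternative chosen after seeing the data, it was 0 at day 14, 43 for the mean and 2 for the interaction, and the lone GFP library is then assumed to vary like the other groups. With only genes present in all per-sample tables, also chosen after seeing the data, every count stayed within 1.5 times, at 31, 5, 83, 0, 0 and 4. The series table proved to hold the same counts as those tested, so it is no separate check. Leaving out 1 library at a time gave 1 to 58 genes at day 7, 0 to 6 at day 14, 26 to 133 for the mean, 0 to 1 for the interaction, 0 for the course with GFP and 0 to 10 for the course with Olig1.

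Lists called by camera numbered 18, 9, 19, 11, 6 and 16 in the same order. With an estimated correlation they numbered 0, 0, 0, 0, 0 and 0, and with fry 14, 1, 12, 1, 1 and 0. Without both GFP day 14 libraries that stood apart they numbered 9 at day 14, 17 for the mean, 8 for the interaction and 5 for the course with GFP. Leaving out a library gave 16 to 20, 8 to 13, 18 to 21, 7 to 16, 6 to 9 and 10 to 18 lists. Genes higher in both days numbered 1 and genes lower in both 0 with the stricter filter, 0 and 0 with a replicate block, and 3 and 1 at an adjusted p of 0.1. Olig1 at day 14 kept its direction but missed the threshold without a filter (11.01, adjusted p = 0.125), with a replicate block (11.29, 0.0648), with only these groups in the fit (11.01, 0.499) and without both GFP day 14 libraries that stood apart (12.54, 0.210). Leaving out a library gave an Olig1 log2 fold change of 11.08 to 12.08 at day 7, 9.56 to 13.35 at day 14 and 10.58 to 12.49 for the mean. Over single lists and settings other than the omission of 1 library, 1696 values stayed on their side of the threshold, 155 lost it and 27 newly passed it, and in omissions of a library these were 2135, 85 and 84. Without the series table they were 1339, 138 and 118 for named genes in the same settings and 1286, 393 and 7 in omissions. The 34 differences of marker sums moved by less than 1 SD with TMM-scaled totals, while their tests cannot pass at 3 against 3. The simulated data show that 4-fold changes are mostly out of reach, and that of the largest simulated changes 55.1% passed at day 7.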

Other observations

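The regeneration ratio was tested after the result was seen. Lists not called in any comparison are given here as values for Olig1 against GFP over both days. Medians were 0.52 for the integrated stress response (adjusted p = 0.0717), with Asns at 2.33, Ddit3 at 2.12, Slc7a3 at 6.72 and Stc2 at 9.13 past the threshold adjusted over the list alone and none over all genes. They were 0.70 for pro-apoptotic genes and 0.01 for anti-apoptotic genes, with no member past either, and 0.79 for p53 targets, where Cdkn1a stood at 4.29 and Sesn1 at -1.72. Brakes on axon regrowth had a median of 0.39, with Rtn4rl2 the only member called, a call lost in 11 of 12 omissions of a library. Trophic factors and receptors had a median of 0.70, with Ret at 6.02, and Notch and basic helix-loop-helix factors -0.71, with Id4 at 4.34, Neurod1 at -2.05 and Neurod4 at -2.15. Medians were 0.22 for JAK-STAT signalling, -0.56 for PI3K and mTOR signalling, -0.02 for Wnt signalling, -1.07 for the cell cycle, -0.39 for autophagy and the lysosome and 0.08 for antioxidant genes. They were 0.15 for heat shock proteins, -0.14 for endoplasmic reticulum chaperones, -1.62 for cytokines and complement and 1.04 for crystallins. Endothelial genes had a median of -0.13, pigment epithelium genes 1.43 and fibroblast genes 1.77.

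Single libraries stood apart in some transcripts. Penk, an opioid precursor and a listed marker of ganglion cell subtypes, stood at 26272 CPM in GFP day 7 replicate 2, against 10.9 and 632 CPM in the other libraries of that group. Erythrocyte markers reached 2630 CPM and fibroblast markers 1169 CPM in Olig1 day 7 replicate 2. Horizontal cell markers averaged 690 ± 764, 212 ± 31.5, 3619 ± 4255 and 7123 ± 4671 CPM (SD, n = 3) in GFP day 7, Olig1 day 7, GFP day 14 and Olig1 day 14. T cell markers stayed at or below 14.1 CPM in every library. CT010467.1, which resembles ribosomal RNA, averaged 10677 ± 2413 and 15468 ± 10378 CPM at day 7 and 671 ± 33.1 and 1010 ± 309 CPM at day 14, in the order GFP and Olig1. It set the days apart in every library rather than single libraries, and batch and day cannot be told apart. Mitochondrial genes held 2.51% to 10.9% of counts.

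The hypothesis that regeneration-associated genes were raised beyond the ganglion cell markers was tested by the log2 ratio of both sums. Olig1 minus GFP was -1.14 at day 7, -0.62 at day 14 and -0.88 on average, the opposite direction. By an exact permutation test within days the p was 0.225 over 400 relabelings, with 0.005 the smallest possible, so the ratio did not differ by more than the spread between libraries. In the GFP libraries the ganglion cell sum was at most 313 CPM and the regeneration sum at least 190 CPM. The sums do not show which cells the regeneration transcripts came from. The ratio thus cannot decide whether they rose within ganglion cells, and the hypothesis stays open.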
